A study of Mus musculus with 19 samples.

How the data were processed

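Gene expression was measured on Affymetrix arrays in type 1 conventional dendritic cells (DC1), the dendritic cell subset specialised in presenting antigen to CD8 T cells, sorted from mice on a C57Bl/6j background. The mice were wild type (WT) or lacked Batf3, a transcription factor gene, and carried or did not carry Irf8VENUS, a fluorescent reporter of Irf8. The spleen part held 8 arrays from female mice and the part from skin-draining lymph nodes (SDLN) held 11 arrays of another array type. The 2 parts were separate tables and were tested only within a table. Per the labels' protocols, RNA was prepared with a micro-scale column kit and labelled with a kit for small amounts of RNA. Where nothing in the labels says that arrays of a group came from separate mice, p-values measure only the spread between arrays, part of which may be technical.

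The deposited spleen values were array intensities on a linear scale, from 1.85 to 13035.5, and log2 was taken before any test. The deposited lymph node values were on a log2 scale, from 1.35 to 13.96. Per the submitters' processing notes, the authors used RMA, which corrects background, quantile normalizes and summarises probes; its version is not given in the sources used here. Neither table gives a measure of background per probe, so signal near the floor could not be set apart from absence, and the number of arrays limits the precision.

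Probe sets were named from the platform annotation, and symbols were updated through gene identifiers in a RefSeq table. For spleen, 23521 of 41345 probe sets had 1 symbol, 1814 had several and 16010 were unnamed. For lymph node, 21789 of 35556 had 1 symbol, 1621 had several and 12146 were unnamed. Gene identifiers matched for 23328 and 21698 probe sets with 1 symbol. Each gene was represented by its probe set with the highest mean, and probe sets with several symbols were left out. A gene was tested when at least 2 arrays reached the median of the table's values, a log2 intensity of 5.04 in spleen and 4.82 in SDLN, which left 12866 of 22151 and 11928 of 19920 genes.

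Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 for a called gene. All arrays of a table shared 1 estimate of the spread. The spleen fit had the sort gate as a term, because replicate 3 of both Irf8VENUS+ groups was sorted on CD24 alone and the other spleen arrays on CD24 and XCR1. The estimated fold changes of comparisons with the Irf8VENUS- group therefore differ from plain differences of means. Fold changes are log2 differences, given with the moderated standard error (SE) of the fit.

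The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. For each comparison but the third spleen one, the rule named Batf3, Irf8 and the genes of the sort gates, the 8 called genes with the largest log2 fold changes in each direction, and up to 2 called members of each list. For the difference of the Batf3 effect it named 5 in each direction, and for a list with no called member it allowed the member with the smallest p. Symbols starting with Gm and digits, ending in Rik or starting with Mir or Snor, and antigen receptor segments, were left out of the largest changes. Other genes named below were chosen after their values were seen. The lists covered cDC1 identity, cDC2 identity, pDC identity, DC maturation and migration, MHC class I and class II presentation, cross-presentation and phagosome, type I interferon response, cell cycle, DC cytokines and chemokines, costimulatory and coinhibitory ligands, DC transcription factors, Toll-like receptors and adaptors, uptake receptors, cholesterol biosynthesis and tissue dissociation stress. Markers of T cells, B cells, NK cells, macrophages and monocytes, neutrophils, Langerhans cells, stromal and endothelial cells and erythroid cells stood for other cells that a sort could hold. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists of a comparison. Genes on a list that the arrays do not name were not analysed here.

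The lymph node titles carry a code shared by arrays of the same replicate number, which reads like a shared day although the labels do not say so. Arrays of the same number were checked for shared deviations from their group means across genes. In Batf3-/- mice the resident and migratory arrays of the same number had correlations of 0.416, 0.210 and 0.478. Replicates 1 and 2 of differing number had 0.184 and 0.218, so the 0.210 of replicate 2 does not set its pair apart. Deviations were thus shared between some of these arrays, but neither these values nor the labels settle whether the numbers pair them. The fits had no block, and fits with the number as a block were alternatives.

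The alternatives were no filter or a stricter filter on dim genes, quantile normalization again, median centring, other variance models, array weights, the mean of all probe sets, only the groups compared, a 2-fold minimum, leaving out each replicate, and blocks or gate terms. Fits with the spread of each array's values as a term, and fits without arrays that stood apart, were added after the data were seen.

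The fits were tested on simulated data in which 200 genes were changed. For spleen Batf3-/- against WT, with 12866 genes, 58% of genes changed by a log2 fold of 1 and 88% of those changed by 2 were recovered. For the 2 spleen comparisons with the Irf8VENUS- group, the shares were 48% and 78% for WT and 42% and 89% for Batf3-/-. With 11928 genes in SDLN, they were 66% and 98% for resident Batf3-/- against WT and 67% and 98% for migratory, and 29% and 89% for the difference between those effects. For migratory against resident they were 54% and 96% in WT, and 70% and 97% in Batf3-/-. The share of false calls was highest for migratory Batf3-/- against WT, 17 of 182 calls, and for migratory against resident WT, 14 of 164. It was lowest for the difference of effects, 3 of 121. Simulated noise was independent between genes and had the same spread on all arrays. These shares therefore do not cover arrays with shared deviations or differing spread, as in the lymph node data.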

Results

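Type 1 conventional dendritic cells (DC1) present antigens taken up from dying cells to CD8 T cells, and their development depends on the transcription factors IRF8 and BATF3. The series profiled DC1 from mice that lack Batf3 and carry Irf8VENUS, a fluorescent reporter of Irf8, beside wild-type (WT) mice. The spleen part held 2 arrays of WT Irf8VENUS- DC1, 3 of WT Irf8VENUS+ DC1 and 3 of Batf3-/- Irf8VENUS+ DC1. The skin-draining lymph node (SDLN) part, all Irf8VENUS+, held 3 arrays of resident WT DC1, 2 of migratory WT DC1, 3 of resident Batf3-/- DC1 and 3 of migratory Batf3-/- DC1. Resident DC1 live in the node, whereas migratory DC1 arrive from the skin, and per the labels they were sorted by their levels of MHC class II and CD11c. Fold changes below are on the log2 scale with their standard error (SE), group levels are log2 intensities with their SD, and adjusted p-values are from limma. The spleen protocol lists CD172a+, a marker of the other conventional subset cDC2, where the SDLN protocol lists CD172-. On the spleen arrays Sirpa, the gene of CD172a, lay at 5.35 to 5.84, near the filter level. The cDC1 identity genes Xcr1 (8.99 to 11.43) and Tlr3 (10.52 to 11.21) were bright, and so was Clec12a of the cDC2 list (9.76 to 10.74). The Sirpa, Xcr1 and Tlr3 values argue against a cDC2 sort, but RNA is not surface protein. How closely the spleen cells match the SDLN cells was not tested. The number of arrays limits the precision.

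The deleted gene was low in each group labelled Batf3-/-. In spleen, Batf3 had a log2 intensity of 6.24 ± 0.90 (SD, n = 3) in Batf3-/- DC1, 9.93 ± 0.42 (n = 3) in WT Irf8VENUS+ DC1 and 9.56 ± 0.20 (n = 2) in WT Irf8VENUS- DC1. In SDLN it was 5.74 ± 0.23 (n = 3) in resident and 6.02 ± 0.15 (n = 3) in migratory Batf3-/- DC1, against 8.38 ± 0.23 (n = 3) and 9.19 ± 0.06 (n = 2) in WT. Irf8 was bright in all groups, and in SDLN its lowest mean, 10.71 ± 0.36 (n = 2), was that of migratory WT DC1.

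**Figure D1:**
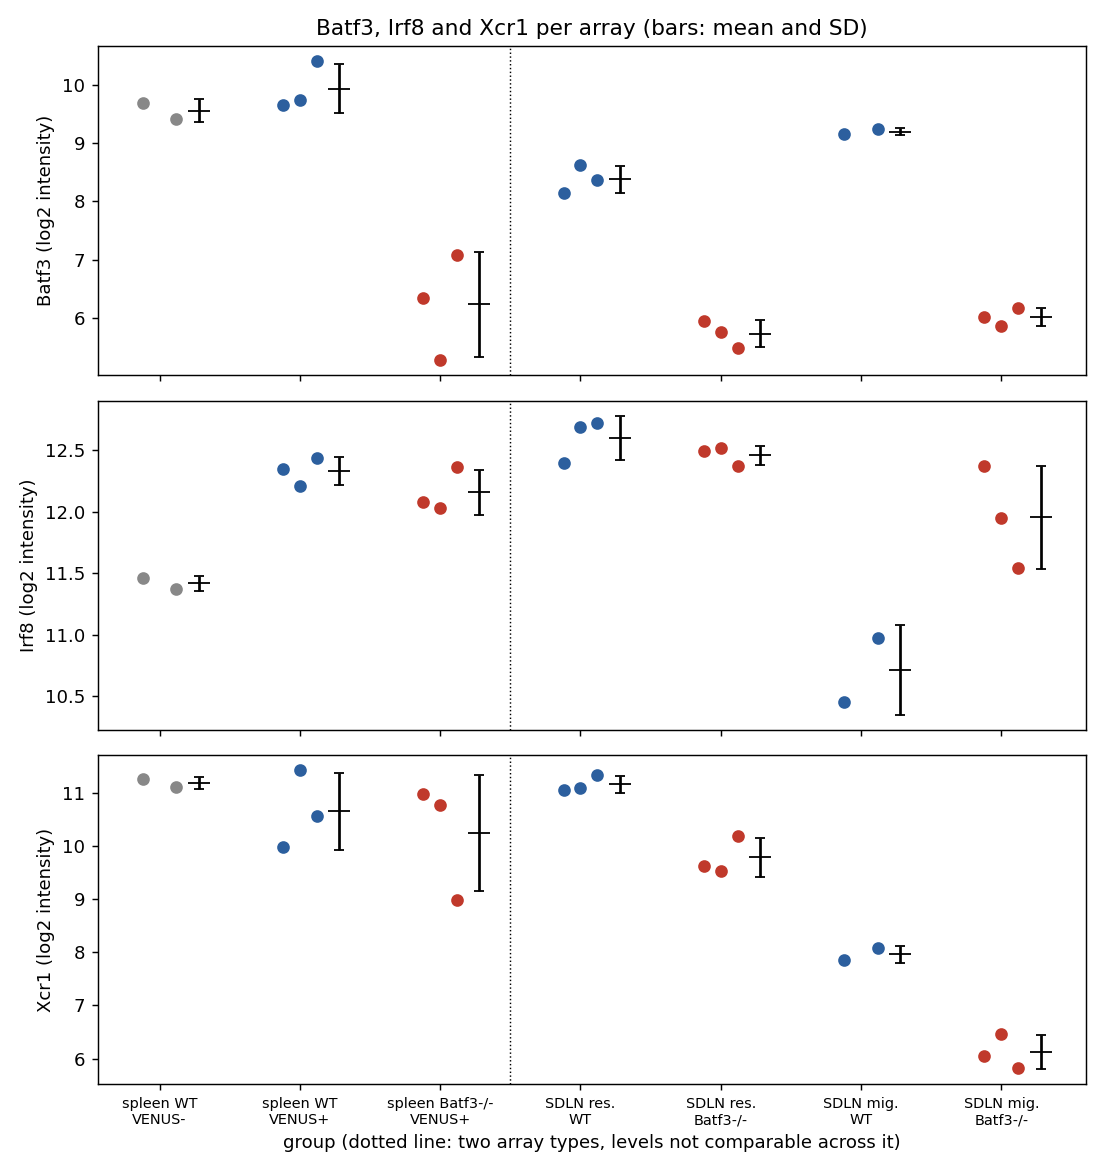
Log2 intensity of Batf3, Irf8 and Xcr1 (vertical axes) on each array, by group (horizontal axis), with points for arrays and bars for the mean and SD. Batf3 in Batf3-/- groups lies below WT in spleen and in both SDLN populations (9.93 against 6.24 in spleen), and the dotted line parts the 2 array types, whose levels cannot be compared.

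The first comparison asked how spleen DC1 that form without Batf3 differ from WT DC1, both Irf8VENUS+ (n = 3 and 3). Batf3 fell by 3.69 ± 0.28 (adjusted p = 0.00193). Among the genes with the largest decreases were Erdr1 (-5.03 ± 0.23), the integrin gene Itga8 (-3.30 ± 0.24), Arhgap42 (-2.57 ± 0.16), Ctla2b (-2.45 ± 0.39), the alkaline phosphatase gene Alpl (-2.38 ± 0.18) and Ppef2 (-1.94 ± 0.21). The largest increases were those of Mcemp1 (2.90 ± 0.15), Zfp872 (2.84 ± 0.33), the cadherin gene Cdh17 (2.81 ± 0.25), the tight junction gene Cldn1 (2.73 ± 0.39), Fabp5 (2.64 ± 0.36), which encodes a fatty acid binding protein, Gbp2b (2.60 ± 0.28), Insl6 (2.51 ± 0.38) and Ms4a6b (2.39 ± 0.25). Of these largest changes, only for Zfp872 and Alpl did both WT Irf8VENUS- arrays lie nearer to Batf3-/- than to WT Irf8VENUS+ DC1. Zfp872 read 7.22 and 7.32 there, against means of 7.93 in Batf3-/- and 5.09 in WT Irf8VENUS+ DC1. Alpl read 6.34 and 6.38, against 5.66 and 8.04. For Insl6 and Ms4a6b, Irf8VENUS- replicate 2 alone lay nearer to Batf3-/-. It read 6.17 for Insl6, against 7.28 and 4.77, and 6.30 for Ms4a6b, against 7.44 and 5.05. Irf8 did not pass the test (-0.17 ± 0.08, adjusted p = 0.537), nor did Itgax, Ptprc, Cd24a, H2-Ab1, Sirpa or Siglech of the sort gates. Xcr1, the chemokine receptor gene that marks DC1, did not pass either (-0.41 ± 0.43), and its difference was 0.17 within the arrays sorted on CD24 and XCR1 and -1.57 within the pair sorted on CD24 alone.

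Of 35 cDC1 identity genes tested, 5 fell and none rose in spleen Batf3-/- DC1, among them Batf3 and the disulfide isomerase gene Pdia5 (-1.97 ± 0.16). Adjusted over the list alone, 14 fell; camera gave an adjusted p of 1.68e-09, and the adjusted p = 0.307 with an estimated correlation. Of 36 DC maturation and migration genes, 3 rose, with 18 higher and 0 lower adjusted over the list alone. They included Fscn1 (1.41 ± 0.19), an actin bundling gene of mature dendritic cells, and Tmem123 (1.30 ± 0.21). The WT Irf8VENUS- arrays read 6.76 and 6.25 for Fscn1, against means of 7.58 in Batf3-/- and 6.17 in WT Irf8VENUS+ DC1. For Tmem123 they read 10.24 and 9.82, against 10.57 and 9.27. The maturation list also had a negative median in WT Irf8VENUS+ against WT Irf8VENUS- DC1, given below, so part of its rise may lie in the WT Irf8VENUS+ group. The adjusted p of that list was 3.54e-19 by camera, and the adjusted p = 0.122 with an estimated correlation. The dissociation stress list lay higher as well, with a median of 0.27 beside 0.53 for the maturation list (camera adjusted p = 0.0197, and adjusted p = 0.346 with an estimated correlation). Of 21 cDC2 identity genes 1 rose, the transcription factor gene Klf4 (1.39 ± 0.22). Of 17 pDC identity genes 1 rose, Lag3 (1.91 ± 0.30), and of 18 cross-presentation genes 1 rose, the NADPH oxidase gene Cybb (1.56 ± 0.15). Of 5 Langerhans cell markers 1 rose, Cldn1. Of 26 DC transcription factors 1 rose and 1 fell. No gene was called of 17 of MHC class I or 14 of MHC class II presentation, 22 of the interferon response, 32 of the cell cycle, 22 cytokines and chemokines, 18 costimulatory and coinhibitory ligands, 17 Toll-like receptors and adaptors, 16 uptake receptors, 16 of cholesterol biosynthesis or 18 of dissociation stress. None of 9 stromal, 6 neutrophil, 9 T cell, 8 B cell, 4 NK cell, 11 macrophage and monocyte or 2 erythroid markers was called.

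In all, limma called 95 of 12866 genes, 56 higher and 39 lower, and the 95 had the same sign within both sort gates. Since the genes were called on the same arrays, such agreement of sign, here and below, is largely fixed in advance and is no replication. WT Irf8VENUS+ replicate 1 had a mean correlation with its group of 0.930, beside 0.939 and 0.946 for replicates 2 and 3, and without it 149 genes were called. The count was 58 without WT replicate 2, 24 without WT replicate 3, and 40, 28 and 25 without Batf3-/- replicates 1, 2 and 3. It was 25 in the arrays sorted on CD24 and XCR1, 46 with only the groups compared and 262 with array weights.

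Between WT spleen DC1 with and without the Irf8VENUS reporter (n = 3 and 2), the comparison asked whether the reporter itself goes with other expression. Limma called 3 genes. Pla2g7, which encodes a platelet-activating factor hydrolase, rose by 2.74 ± 0.24 (adjusted p = 0.038) and the sulfotransferase gene Sult1a1 by 1.83 ± 0.19 (adjusted p = 0.0443), and Klra5, of the Ly49 receptor family, fell by 2.01 ± 0.21 (adjusted p = 0.0443). Klra5 read 4.32, 4.28 and 6.18 on Irf8VENUS+ replicates 1, 2 and 3, and 6.40 and 6.49 on the Irf8VENUS- arrays. The gate term takes up part of the deviation of replicate 3, which was sorted on CD24 alone. The calls of Pla2g7, Sult1a1 and Klra5 were lost in 6, 9 and 10 of 17 alternatives. Irf8 differed by 0.83 ± 0.10, at 12.33 ± 0.11 against 11.42 ± 0.06, with every Irf8VENUS+ array above both Irf8VENUS- arrays, but an adjusted p of 0.0601 left it outside the threshold. No list had a called member. By camera 10 lists passed, and 0 with an estimated correlation. Among them the DC maturation list had a median of -0.36 (camera adjusted p = 5.10e-07, and adjusted p = 0.246 with an estimated correlation), the dissociation stress list -0.49 (7.34e-04 and 0.246) and the macrophage and monocyte markers -0.15 (0.0199 and 0.246). At an unadjusted p under 0.05 there were 1017 genes, with 643.3 given by chance. The count was 0 without Irf8VENUS- replicate 1 or Irf8VENUS+ replicate 2, 1 without Irf8VENUS- replicate 2, 15 without Irf8VENUS+ replicate 1, 0 with only the groups compared or with the replicate number as a block in place of the sort gate (3 with neither block nor gate), 1 without the filter on dim genes or with median centring, and 18 with array weights. At an unadjusted p under 0.05, limma gave 759 genes with only the groups compared, 976 and 594 without Irf8VENUS- replicates 1 and 2, and 1294 without Irf8VENUS+ replicate 2.

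Spleen Batf3-/- Irf8VENUS+ DC1 against WT Irf8VENUS- DC1 (n = 3 and 2) gave 72 called genes, 36 higher and 36 lower. Batf3 fell by 3.65 ± 0.33, and Erdr1 by 4.83 ± 0.27, whereas Mcemp1 rose by 2.82 ± 0.18 and Irf8 by 0.66 ± 0.10 (adjusted p = 0.0325), the genes here chosen after their values were seen. Of 35 cDC1 identity genes 1 rose and 5 fell (adjusted p = 0.39 with an estimated correlation). The count was 10 and 6 without Irf8VENUS- replicates 1 and 2, 36, 23 and 38 without Batf3-/- replicates 1, 2 and 3, and 164 with array weights.

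In resident SDLN DC1, Batf3-/- against WT (n = 3 and 3), Batf3 fell by 2.64 ± 0.17 (adjusted p = 7.85e-06) and Xcr1 by 1.38 ± 0.21 (adjusted p = 0.00409), while Irf8 did not pass (-0.14 ± 0.18, adjusted p = 0.974). Further large decreases were those of Fcrla (-3.24 ± 0.44), Gcsam (-3.03 ± 0.17), Itga8 (-2.95 ± 0.19), BC028528 (-2.67 ± 0.27), Arhgap42 (-2.46 ± 0.20), the fatty acid elongase gene Elovl6 (-2.32 ± 0.19) and the scavenger receptor gene Cd36 (-2.29 ± 0.28). The largest increases were those of Serpinb10 (3.70 ± 0.28), the urokinase receptor gene Plaur (2.62 ± 0.51), Gfra2 (2.57 ± 0.32), Ms4a6d (2.55 ± 0.32), Klrb1b (2.47 ± 0.18), Tlr1 (2.46 ± 0.33), the lectin gene Clec10a (2.42 ± 0.28) and Timd4 (2.21 ± 0.27), which encodes a receptor for phosphatidylserine.

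Of 34 cDC1 identity genes tested in resident DC1, 10 fell and none rose (1 higher and 14 lower adjusted over the list alone; camera adjusted p = 7.31e-15, and adjusted p = 0.0338 with an estimated correlation). Of 37 DC maturation and migration genes, 4 rose and none fell, among them the chemokine genes Ccl17 (adjusted p = 2.46e-04) and Ccl22 (1.74 ± 0.35), with 14 higher and 1 lower adjusted over the list alone. Its median was 0.45, with a camera adjusted p of 1.44e-11 and an adjusted p = 0.445 with an estimated correlation. Of 22 cDC2 identity genes 2 rose, Clec10a and Mgl2 (1.38 ± 0.20), and 1 fell. Sirpa did not pass (-1.03 ± 0.49, adjusted p = 0.546), but resident WT replicate 1 stood apart. It read 7.82 for Sirpa, beside 5.31 and 5.67 on WT replicates 2 and 3, although the sort was CD172-. Clec10a (6.32) and Mgl2 (6.33) were also highest there among the WT arrays, whereas Klf4 (8.33) and Ccr2 (8.41) were lowest. Whether that array held other cells was not tested. Of 15 uptake receptors 1 rose, Timd4, and 3 fell, Cd36 among them. Of 29 DC transcription factors 1 rose and 2 fell, Batf3 and Mycl (-1.11 ± 0.23). Gbp3, of the interferon list, rose by 0.76 ± 0.17, and Vsir, a coinhibitory ligand, fell by 0.82 ± 0.18. The T cell markers had a median of 0.46 with none of 15 called (camera adjusted p = 2.60e-05, and adjusted p = 0.445 with an estimated correlation). Of 13 Toll-like receptors and adaptors 1 rose, Tlr1, and of 25 cytokine and chemokine genes 2 rose and 1 fell. No gene was called of the pDC, MHC class I, MHC class II, cross-presentation, cell cycle, cholesterol, stress, NK cell, macrophage and erythroid lists. The 3 Langerhans cell markers tested had a median of 1.13, above that of the maturation list, with 1 called (camera adjusted p = 0.00447, and adjusted p = 0.445 with an estimated correlation). Other cells' markers that rose were Cldn1 (1.35 ± 0.19) and the endothelial marker Pecam1 (2.11 ± 0.20).

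Limma called 219 of 11928 genes, 101 higher and 118 lower, and the 219 had the same sign within the arrays of each of the 3 title codes. Batf3 differed by -2.19, -2.86 and -2.87 and Ccl17 by 1.87, 2.04 and 2.08 within the codes. The count was 117 and 128 without Batf3-/- replicates 1 and 2, and 157, 95 and 99 without WT replicates 1, 2 and 3. It was 336 with only the groups compared and 980 with array weights.

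In migratory SDLN DC1, Batf3-/- against WT (n = 3 and 2), Batf3 fell by 3.17 ± 0.20 (adjusted p = 1.35e-05) and Xcr1 by 1.85 ± 0.24 (adjusted p = 0.00259). Irf8 rose by 1.24 ± 0.21 (adjusted p = 0.00833), with differences of 1.91 and 0.98 within the 2 title codes that hold both genotypes. The largest increases were those of the integrin gene Itga1 (2.89 ± 0.31), Tubb2b (2.26 ± 0.35), L1cam (2.09 ± 0.43), Castor2 (2.01 ± 0.44), Mex3b (1.95 ± 0.27), Sned1 (1.93 ± 0.32), Plxdc1 (1.93 ± 0.31) and Rasa4 (1.93 ± 0.32). Large decreases were those of the neuropeptide gene Gal (-2.63 ± 0.35), Ifi205 (-2.62 ± 0.26), Plac8 (-2.59 ± 0.51), the growth factor gene Bmp2 (-2.43 ± 0.27), Il23r (-1.96 ± 0.24) and the lectin gene Clec12a (-1.90 ± 0.16).

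Of 34 cDC1 identity genes tested in migratory DC1, 3 rose and 10 fell, Ifi205 and Batf3 the furthest (camera adjusted p = 0.00125, and adjusted p = 0.846 with an estimated correlation). Of 37 DC maturation genes, 7 rose and none fell, among them Apol7c (1.92 ± 0.43) and Pdcd1lg2 (1.52 ± 0.32), which encodes a ligand of PD-1 (camera adjusted p = 0.0104, and adjusted p = 0.909 with an estimated correlation). Of 15 MHC class I genes 2 rose, Tapbpl (0.92 ± 0.24) and the peptide transporter gene Tap1 (0.87 ± 0.20). Of 13 MHC class II genes 3 rose, H2-Eb1 (0.78 ± 0.13) and Ifi30 (0.73 ± 0.17) among them, and 2 fell. Of 13 Toll-like receptor genes 4 rose, among them Tlr13 (1.57 ± 0.34) and Myd88 (1.26 ± 0.31), and 1 fell. The chemokine gene Cxcl9 fell by 1.42 ± 0.20 and the lectin gene Clec9a by 0.92 ± 0.20, while Tnf rose by 1.40 ± 0.35. Of 17 dissociation stress genes 3 rose, Atf3 (1.34 ± 0.26) and Dusp1 (0.90 ± 0.22) among them. With the spread of array values as a term the rises of Tnf, Atf3 and Dusp1 did not pass, at -0.05 for Tnf, 1.07 for Atf3 and -0.03 for Dusp1. Of 13 B cell markers 2 fell, Cxcr5 (-1.73 ± 0.37) and Ms4a1 (-1.30 ± 0.26), and the list had a median of -0.98 (camera adjusted p = 8.28e-07, and adjusted p = 0.846 with an estimated correlation). Of 19 cross-presentation genes 3 rose and 3 fell, of 29 transcription factors 5 rose and 1 fell, of 22 interferon response genes 2 rose and 1 fell, and of 20 costimulatory ligands 2 rose. Of 15 uptake receptors 2 fell, and none of the 32 cell cycle, 16 cholesterol or 15 T cell genes was called. Ccl19, of the stromal and endothelial list, fell by 1.60 ± 0.32, and the macrophage markers C1qa (0.92 ± 0.20) and C1qb (0.61 ± 0.17) rose. Ccl19 was higher in migratory than in resident DC1 of both genotypes, so it need not mark stromal cells here.

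Limma called 1122 genes, 851 higher and 271 lower, and the 1122 had the same sign within both title codes. With the title code as a block 2462 were called. Normalizing again by quantiles gave 713 higher and 429 lower, and testing without the filter on dim genes 965 higher and 1135 lower. The spread of values within an array went with genotype: its SD was 1.96 and 2.03 on the WT arrays and 2.16, 2.15 and 2.07 on the Batf3-/- arrays. With this spread as a term 37 genes were called, 6 higher and 31 lower, and Irf8 differed by 0.43. The count was 109 without WT replicate 1, 224, 242 and 3569 without Batf3-/- replicates 1, 2 and 3, 7 with only the groups compared and 2292 with array weights.

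The difference between the Batf3 effects in migratory and resident DC1 was tested as an interaction. Klrb1b (-2.87 ± 0.27, adjusted p = 7.35e-04), Tlr1 (-2.91 ± 0.50), Ms4a4c (-2.70 ± 0.53), Pecam1 (-2.57 ± 0.31) and Bmp2 (-2.56 ± 0.36) had lower effects in migratory cells. Tubb2b (2.90 ± 0.47), Itga8 (2.51 ± 0.29), Elovl6 (2.41 ± 0.28), Pi4k2a (2.33 ± 0.44) and the Wnt receptor gene Fzd1 (2.25 ± 0.30) had higher ones. Klrb1b differed by 2.47 in resident and by -0.39 in migratory DC1. Itga8, Elovl6 and Fzd1 had WT means of 3.93, 4.73 and 4.57 in migratory DC1 and Bmp2 one of 4.005 in resident DC1, under the level that the filter asked for. That level is a median and not a floor, but these genes had little room to fall there, so their differences need not show an effect of another size. In all this held for 27 of the genes called by the interaction. Irf8 had a difference of 1.38 ± 0.28 (adjusted p = 0.0401). Of the lists, 4 of 34 cDC1 identity genes had higher and 2 lower effects, Fzd1 and Snx22 (2.13 ± 0.39) among the higher (adjusted p = 0.778 with an estimated correlation). Snx22 read 5.02 and 5.54 on the migratory WT arrays, under its 5.91, 5.62 and 6.30 on the resident Batf3-/- arrays. It too had little room to fall, although it lay above the filter level and is not among the 27. Of 22 cDC2 identity genes 3 had lower effects, Clec10a (-2.29 ± 0.41) and Mgl2 (-1.42 ± 0.30) among them. On the migratory arrays Clec10a (3.40 to 4.27) and Mgl2 (4.07 to 4.34) lay under the filter level in both genotypes. Their differences thus show a rise in resident DC1 of genes that were dim in migratory DC1. The chemokine genes Ccl17 (-1.67 ± 0.32) and Cxcl9 (-1.53 ± 0.27) had lower effects. Markers of other cells had the lowest camera p-values: the 13 B cell markers had a median of -0.998 (camera adjusted p = 2.04e-05, and adjusted p = 0.778 with an estimated correlation) and the 15 T cell markers -0.36 (1.98e-04 and 0.778), with none of them called.

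The interaction called 149 genes, 86 higher and 63 lower, around a median of 0.12 over all genes tested, which was 0.06 after quantile normalization again and 0.21 with median centring. The balance turned without the filter on dim genes, to 109 higher and 189 lower around a median of -0.04, and with the spread of array values as a term, to 8 higher and 22 lower. With the title code as a block 543 were called and with median centring 73. The count ran from 17 without resident WT replicate 2 to 1712 without migratory Batf3-/- replicate 3. It was 18 without resident WT replicate 3, 69 without resident WT replicate 1, 35 and 329 without migratory WT replicates 1 and 2, 39, 36 and 66 without resident Batf3-/- replicates 1, 2 and 3, and 45 and 47 without migratory Batf3-/- replicates 1 and 2. Some of these fits turned the balance as well. They gave 14 higher and 21 lower without migratory WT replicate 1, and 30 and 36 without resident Batf3-/- replicate 3. Without migratory Batf3-/- replicates 1 and 2 the splits were 22 and 23, and 23 and 24.

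Migratory against resident DC1 was compared within each genotype (n = 2 and 3 in WT, 3 and 3 in Batf3-/-). In WT, the largest increases in migratory DC1 were those of Atxn1 (5.85 ± 0.33), the cytokine signalling inhibitor gene Socs2 (5.42 ± 0.40), Insl6 (5.40 ± 0.26), the tetraspanin gene Cd63 (5.26 ± 0.53), H2-M2 (5.15 ± 0.38), Serpinb1a (5.01 ± 0.23), Anxa3 (4.93 ± 0.39) and Slco5a1 (4.91 ± 0.32). The largest decreases were those of Naaa (-5.41 ± 0.46), Rab7b (-4.69 ± 0.36), the double-stranded RNA receptor gene Tlr3 (-4.41 ± 0.25), Treml4 (-4.37 ± 0.33), P2ry6 (-4.37 ± 0.26), Cyth4 (-4.36 ± 0.27), Slamf8 (-4.11 ± 0.45) and the chemokine receptor gene Ccr2 (-3.98 ± 0.27). Xcr1 fell by 3.20 ± 0.24, Irf8 by 1.88 ± 0.21, Itgax by 2.07 ± 0.37 and H2-Ab1 by 0.73 ± 0.09, and Batf3 rose by 0.81 ± 0.20.

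Of 37 DC maturation genes 33 rose and 1 fell in migratory WT DC1 (adjusted p = 0.179 with an estimated correlation), and the 32 cell cycle genes tested fell, Ccna2 (-3.20 ± 0.19) and Ccnb2 (-3.04 ± 0.24) the furthest (adjusted p = 0.179 with an estimated correlation). Of 34 cDC1 identity genes 3 rose and 28 fell (adjusted p = 0.162 with an estimated correlation), and of 17 dissociation stress genes 14 fell, Nr4a1 (-3.13 ± 0.73) and Jun (-2.44 ± 0.42) the furthest (adjusted p = 0.402 with an estimated correlation). Of 13 MHC class II genes 1 rose, Lgmn (2.75 ± 0.29), and 8 fell, the transactivator gene Ciita (-3.25 ± 0.24) the furthest. Of 13 Toll-like receptor genes 1 rose and 9 fell. Of 19 cross-presentation genes 7 fell, Wdfy4 (-3.76 ± 0.34) and Clec9a (-3.07 ± 0.20) among them, and of 15 uptake receptors 2 rose and 10 fell. Of 25 cytokine and chemokine genes 13 rose, Ccl5 (4.62 ± 0.52) and Il15 (3.48 ± 0.39) among them, and 7 fell. Of 20 costimulatory and coinhibitory ligands 8 rose, Cd70 (3.40 ± 0.32) among them, and 7 fell, with Havcr2 (-3.57 ± 0.35). Of 16 cholesterol biosynthesis genes 5 rose, with Idi1 (2.75 ± 0.16) and Fdft1 (1.96 ± 0.34), and 2 fell.

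Other lists had called genes in both directions in migratory WT DC1. Of 22 interferon response genes 8 rose and 5 fell, with Ifit1 at 2.73 ± 0.38 and Irf7 at -2.52 ± 0.30. Of 29 DC transcription factors 7 rose and 9 fell, Mycl (-3.81 ± 0.25) and Klf4 (-2.61 ± 0.32) among the latter. Of 15 MHC class I genes 3 rose and 6 fell, of 22 cDC2 identity genes 5 rose and 10 fell, and of 19 pDC identity genes 3 rose and 5 fell. Among markers of other cells, 12 of 13 B cell markers rose and 1 fell (adjusted p = 0.402 with an estimated correlation), with Cxcr5 at 2.47 ± 0.37, and 7 of 15 T cell markers rose and 0 fell (adjusted p = 0.426 with an estimated correlation), with Il7r at 3.31 ± 0.39. Of 8 macrophage and monocyte markers 4 rose and 2 fell, of 4 NK cell markers 1 rose, of 3 Langerhans cell markers 1 rose and 1 fell, of 10 stromal and endothelial markers 1 rose, Ccl19 (3.19 ± 0.32), and of 2 erythroid markers 1 rose.

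In Batf3-/- DC1 the largest increases in migratory cells were those of Atxn1 (4.72 ± 0.29), Serpinb1a (4.71 ± 0.21), H2-M2 (4.53 ± 0.34), Slco5a1 (4.51 ± 0.28), Il15 (4.41 ± 0.35), Socs2 (4.36 ± 0.36), Anxa3 (4.36 ± 0.35) and Insl6 (4.31 ± 0.23). The largest decreases were those of Tlr3 (-5.02 ± 0.22), Naaa (-4.97 ± 0.41), Ms4a6c (-4.54 ± 0.38), Ccr2 (-4.52 ± 0.24), Scimp (-4.51 ± 0.24), the chemokine gene Ccl3 (-4.40 ± 0.41), Entpd1 (-4.33 ± 0.37) and Ifi205 (-4.31 ± 0.23). Xcr1 fell by 3.67 ± 0.21 and Irf8 by 0.51 ± 0.18 (adjusted p = 0.0488), with Irf8 differences of -0.12, -0.57 and -0.83 within the 3 title codes. Of 37 DC maturation genes 33 rose and 1 fell (adjusted p = 0.148 with an estimated correlation). All 32 cell cycle genes tested fell, of 34 cDC1 identity genes 3 rose and 25 fell, and for both lists the adjusted p = 0.148 with an estimated correlation. Of 17 dissociation stress genes 10 fell (adjusted p = 0.45 with an estimated correlation). Of 13 MHC class II genes 1 rose and 9 fell, of 15 MHC class I genes 7 rose and 3 fell, and of 25 cytokine and chemokine genes 14 rose and 7 fell. Of 13 B cell markers 2 rose, and of 15 T cell markers 1.

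**Figure D2:**
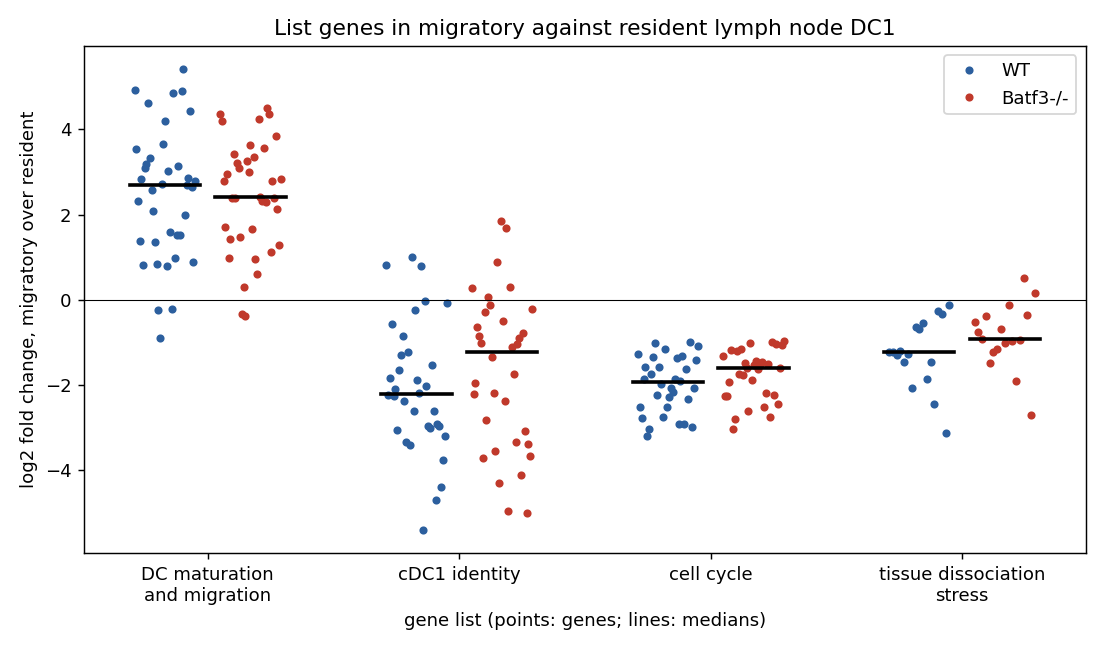
Log2 fold change of migratory over resident SDLN DC1 (vertical axis) for each tested gene of 4 lists (horizontal axis), in WT and in Batf3-/- mice, with lines for medians. The DC maturation genes have medians of 2.70 in WT and 2.40 in Batf3-/-, and the cell cycle genes -1.94 and -1.60.

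Limma called 5868 genes between migratory and resident WT DC1, 1903 higher and 3965 lower, around a median of -0.16 over all genes tested, and 4371 in Batf3-/- DC1, 1677 higher and 2694 lower. With median centring the WT split was 1304 higher and 4663 lower, around a median of -0.32, and without the filter on dim genes it turned to 4857 higher and 4008 lower, around a median of 0.12. With the spread of array values as a term the WT count was 1264, 735 higher and 529 lower, and Nr4a1 differed by 2.09, Itgax by 0.24 and Cd3g, a T cell marker at 1.73 ± 0.64 otherwise, by -0.74. Within each title code, 5858 of the 5868 genes and 4345 of the 4371 had the same sign.

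The Batf3 effects in the 3 populations were compared over genes tested on both arrays, and the pairs share no arrays. Between spleen and resident SDLN DC1, 27 genes were higher in both, against 0.487 given by independent lists, 25 were lower in both, against 0.398, and 0 went opposite ways (Fisher's exact test, one-sided, p = 1.15e-42 and 2.46e-42). The fold changes of 10033 genes had a Pearson correlation of 0.582 and a Spearman correlation of 0.383 across genes, which are not independent replicates. Between spleen and migratory DC1, 13 genes were higher in both, against 4.14, and 5 lower in both, against 0.597 (p = 1.59e-04 and 2.91e-04, the same exact test). The exact test takes genes as independent, so its p-values do not measure the spread between arrays. Each count of genes lower in both Batf3 effects holds Batf3, the deleted gene. Between resident and migratory DC1, 22 were higher in both, against 7.21, 14 lower in both, against 2.68, and 3 went opposite ways, Arpin, Lipa and Tubb2a, named after their values were seen. Since some Batf3-/- resident and migratory arrays share deviations, these 2 lists are not independent, and part of their overlap may come from that. Migratory against resident differences shared 987 higher and 2307 lower genes between genotypes, against 268 and 896, with 27 in opposite directions and a Pearson correlation of 0.841.

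**Figure D3:**
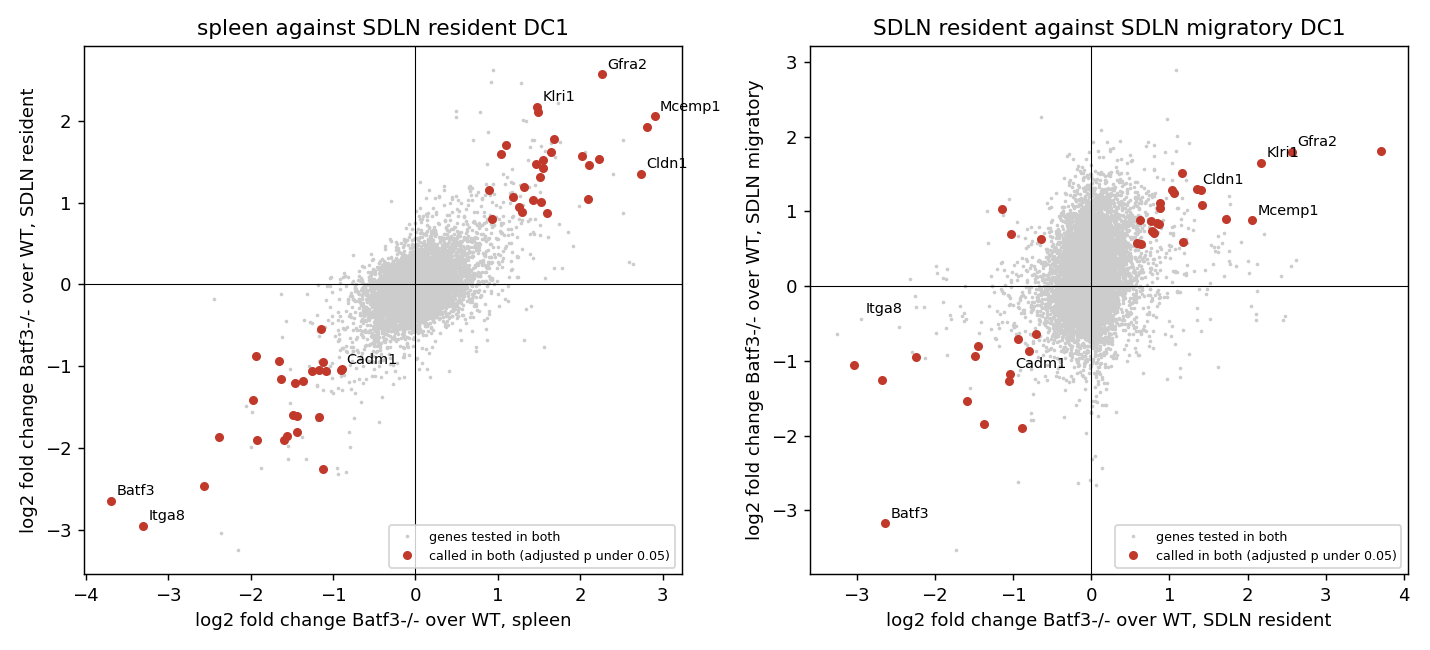
Log2 fold change of Batf3-/- over WT for each gene tested in both populations, spleen (horizontal) against resident SDLN DC1 (vertical) at left and resident (horizontal) against migratory (vertical) at right, with genes called in both in red. The correlation across genes was 0.582 at left and 0.218 at right, and Batf3 is lower in both panels.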

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

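The interaction between genotype and population was a planned test, while the count of genes with little room to fall and the tests that use the spread of array values, the dilution of a sort, the share of migratory cells and the stress genes were chosen only after the results were seen.

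The Batf3 effect differed between migratory and resident DC1 for 149 genes by the interaction test. The furthest differences, migratory minus resident on the log2 scale, were 2.90 for Tubb2b, 2.51 for Itga8, 2.41 for Elovl6, 2.33 for Pi4k2a, 2.25 for Fzd1, -2.91 for Tlr1, -2.87 for Klrb1b, -2.70 for Ms4a4c, -2.57 for Pecam1 and -2.56 for Bmp2. For 27 of the 149, Itga8, Elovl6, Fzd1 and Bmp2 among them, WT levels in the population with the smaller effect lay under the level of the filter, so there was little room for a fall there. Klrb1b, which had room to rise in both populations, passed the test in each alternative that was run.

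Of the genes called between migratory Batf3-/- and WT DC1 851 were higher and 271 lower, but the balance turned to 53 and 56 without WT replicate 1, 965 and 1135 without the filter on dim genes, 6 and 31 with the spread of array values as a term and 2 and 5 with only the groups compared. If differing spread between arrays, narrowest in WT, as from RNA quality, were behind these calls, the resident Batf3-/- array with the narrower spread should differ from the other 2 in the opposite direction at the same genes, and it did at 77.7% of them, against 65.8% of all genes. With the spread as a term the median change of the 1122 genes, taken in the direction called, went from 0.92 to 0.39, the median SE from 0.21 to 0.28, and 1028 kept their sign, so many calls may owe part of their size to it. Cells of another type in the WT migratory sort cannot be told apart from an effect of Batf3, because the DC maturation genes, which dilution would raise in Batf3-/- DC1 as much as the other genes called higher, had a median of 0.50 with quartiles of 0.20 and 0.96, beside a median of 0.94 for those genes. Markers of other cells bear on it as well. The B cell markers lay lower in migratory Batf3-/- than WT DC1 as a list by camera, but not with an estimated correlation. Cxcr5 differed by -1.73 (means of 4.54 in Batf3-/- and 6.27 in WT) and Ms4a1 by -1.30 (4.55 and 5.85). Lower B cell markers go with B cells in the WT sort. The macrophage markers C1qa (0.92, means of 5.67 and 4.74) and C1qb (0.61, 5.61 and 5.00) went the other way. No T cell marker was called. For each of these named markers the lower mean lay near or under the filter level of 4.82. They therefore do not settle whether the WT sort held B cells. An effect of Batf3 stays open too, since in the migratory arrays spread and genotype go together.

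Of 37 maturation genes, 4 were called higher in resident Batf3-/- DC1, Ccl17, Ccl22, Ccr7 and Tnfrsf4, singled out after their values were seen, and for the list the adjusted p = 0.445 with an estimated correlation. Migratory DC1 within the resident gate would bring all genes that are high in migratory cells: 10 such genes gave a median share of 2.03% (0.219% to 2.92% from group means), while Ccl17, Ccl22 and Ccr7 would need 13.7% to 30.5%. Shares varied between arrays, with up to 7.97% for Socs2 on replicate 1 and down to 5.48% for Ccl22 on replicate 3. On each array these 3 genes needed more than any of the 10 gave. But the 10 were chosen as at least 16-fold higher in migratory than in resident DC1 of both genotypes. That rule leaves out genes raised in resident Batf3-/- DC1 and so keeps the shares low. Such cells therefore cannot be told apart from a change in Ccl17, Ccl22 and Ccr7. Tnfrsf4 would need 3.74%, which lies within the spread of the 10 genes between arrays, so such cells may account for it and cannot be told apart from a change in the gene. Release of stress genes during dissociation is argued against by their median of 0.0445 (quartiles -0.10 and 0.20), beside at least 1.07 for the called maturation genes. A higher expression of these 4 genes in Batf3-/- resident DC1 remains a hypothesis, found and tested on the same arrays.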

How the results depend on the processing

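The counts of genes called moved with the settings as given below, and the cause was not tested beyond the spread of array values. The block changed no call by over 1.5-fold besides those given below. Arrays of the same number had correlations of -0.03, 0.21 and -0.02 between resident WT and Batf3-/- arrays, -0.16 and 0.25 between migratory ones, 0.15 and 0.10 between WT resident and migratory ones, and -0.07, 0.27 and 0.35 between the spleen genotypes.

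With array weights the counts were 262 and 18 for spleen Batf3-/- against WT and the reporter, 164 for spleen Batf3-/- against Irf8VENUS-, 980 in resident, 2292 in migratory DC1 and 1110 for the difference of effects. With only the groups compared they were 46, 0, 336 and 7 for spleen, the reporter, resident and migratory DC1. Sorted on CD24 and XCR1 alone, spleen gave 25 and, against Irf8VENUS-, 38. At 2-fold or more resident, migratory, WT and Batf3-/- population counts were 136, 456, 2707 and 1875. Without the filter on dim genes the reporter gave 1 (1385 at an unadjusted p under 0.05), migratory DC1 2100, the difference of effects 298 and WT populations 8865. With median centring the reporter gave 1 (1078) and the difference 73. The replicate number as a block in place of the sort gate gave 0 (1044) for the reporter, where 2 choices changed at once. As a block, the title code gave 2462 in migratory DC1 and 543 for the difference, which as a random effect was 285. With the spread as a term the counts were 428, 37, 30 and 1264 for resident, migratory, the difference and WT populations, and with the narrowest migratory Batf3-/- array alone 41. The spleen and resident overlap had 85 genes at an unadjusted p under 0.01 and 2-fold, and the resident and migratory overlap 77 with covariates switched. With an estimated correlation 0 lists were called, and 1 in resident DC1.

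Leaving out 1 array gave 24 to 149 for spleen, 0 to 15 for the reporter, 6 to 38 against Irf8VENUS-, 95 to 176 in resident, 109 to 3569 in migratory DC1, 17 to 1712 for the difference, 4107 to 5272 for WT and 3453 to 4361 for Batf3-/- populations. Named genes lost their call in 71 of 378 values for spleen, 25 of 51 for the reporter, 32 of 475 in resident, 184 of 752 in migratory DC1, 120 of 417 for the difference, 28 of 984 for WT and 29 of 969 for Batf3-/- populations.

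Some genes changed sign. Of these, Syk, Ifit3, Tnf and Dusp1 in migratory DC1 and Itgax, Nr4a1 and Cd3g between WT populations had been called, and they did so with the spread as a term. In spleen Batf3-/- against WT: H2-Ab1 -0.0494, -0.062 to 0.12 by array left out, Siglech -0.45 to 0.17 by array left out, Xcr1 0.17, -0.99 to 0.17 by array left out. In the reporter comparison: Xcr1 0.23, -0.50 to 0.53 by array left out, H2-Ab1 0.0521, -0.16 to 0.0735 by array left out, Sirpa -0.24 to 0.0571 by array left out, Batf3 -0.0964 to 0.18 by array left out, Siglech -0.00435 to 0.62 by array left out. In resident Batf3-/- against WT: Siglech -0.0198, -0.0546, -0.27 to 0.29 by array left out, Cd24a -0.28 to 0.0134 by array left out, H2-Ab1 -0.0909 to 0.0153 by array left out. In migratory Batf3-/- against WT: Sirpa -0.36 to 0.0516 by array left out, Siglech 0.48, 0.14, -0.23 to 0.10 by array left out, Ptprc -0.25, Itgax -0.58, -0.18, Cd24a 0.46, 0.0984, Syk -0.0603, Ifit3 0.26, Tnf -0.0462, Dusp1 -0.0314. In the difference of effects: Ptprc -0.00278, -0.54, Itgax -0.0719, -1.36, -0.11 to 0.70 by array left out, Siglech 0.0145, 0.53, -0.36 to 0.20 by array left out, Cd24a 0.0134, 0.64, -0.21 to 0.0919 by array left out, H2-Ab1 0.0386, -0.10 to 0.00587 by array left out. In WT migratory against resident: Sirpa -0.82 to 0.44 by array left out, Itgax 0.24, Nr4a1 2.09, Cd3g -0.74. Single values come from scaling, weights, the block, the gate or the spread term.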

Other observations

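The tests of Mid1, of neighbours of Batf3 and of the genes called in all populations were chosen only after the results were seen, and the counts of other splits of the arrays were planned.

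The same 11 genes were called in the same direction in spleen, resident and migratory Batf3-/- DC1, 8 of them higher and 3 lower. Batf3, Mcemp1, Cldn1 and Gfra2 came under the rule for named genes, and the others were named after their values were seen. The higher ones were Gfra2, a receptor gene of the GDNF family (2.26 in spleen, 2.57 in resident and 1.80 in migratory DC1), the NK receptor family gene Klri1 (1.48, 2.17 and 1.65), Mcemp1 (2.90, 2.06 and 0.88), Cldn1 (2.73, 1.35 and 1.30), the Src family kinase gene Fgr (1.54, 1.42 and 1.08), the choline kinase gene Chka (1.60, 0.87 and 0.84), Rras2 (1.29, 0.89 and 1.11) and Bmp2k (0.93, 0.80 and 0.71). The lower ones were Batf3, the adhesion gene Cadm1, which marks DC1 (-0.90, -1.04 and -1.17), and Fxyd5 (-1.08, -1.05 and -1.27). The count depends on the migratory calls: only Batf3 kept its migratory call with the spread of array values as a term or with only the groups compared, Batf3 and Cadm1 did without WT replicate 1, and all 11 kept their sign in each of these fits. Whether these effects differed in size between spleen and SDLN was not tested, since the tissues were on different array types.

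Erdr1 had the largest decrease in spleen Batf3-/- DC1, -5.03, and was not analysed here in SDLN. A candidate explanation is a variant of the X chromosome end that holds Erdr1 and Mid1, carried by the Batf3-/- mice. It predicts a change in Mid1 as well, and Mid1, chosen after its values were seen, differed by -2.06 ± 0.37 in spleen (adjusted p = 0.0548), -1.49 in resident and -0.93 in migratory DC1. Regulation of the region by Batf3 predicts the same, so these cannot be told apart. DNA of another strain around the Batf3 locus would place the called genes near Batf3, but among the 250 protein-coding genes on either side only 1 of the genes called in spleen was found, Fcer1g, with 93 elsewhere, and 2 of those called in resident DC1, Fcgr2b and Fcrla, with 216 elsewhere, which argues against it as the source of most calls.

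Other splits of the same arrays were counted for comparisons of 3 against 3, whose 10 splits are too few for a share under 0.05. In spleen Batf3-/- against WT, 2 of the 10 splits called as many genes, the real one with 95 and another with 420. With the sort gate as a term, that other split equals WT Irf8VENUS+ replicate 1 against WT replicate 2 and Batf3-/- replicates 1 and 2, so it sets a single array against 3 and its count decides nothing. Without the gate term it called 44. In resident DC1 1 of 10 splits, the real one, called as many (219, with 1 as the highest other). In migratory against resident Batf3-/- DC1 it was 1 of 10 as well (4371, with 0 as the highest other). These splits ignore the replicate numbers, although some of these arrays share deviations.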
